A study of Caenorhabditis elegans with 12 samples.

How the data were processed

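Whole Caenorhabditis elegans were profiled by mRNA sequencing at day 7 of adulthood. There were 6 libraries of N2, the laboratory wild type, and 6 of the xpf-1(tm2842) mutant, which lacks a working XPF-1 nuclease of the nucleotide excision repair pathway. Groups and replicate numbers were taken from the sample titles. The library titled N2 replicate 6 carries the N2 strain label but a mutant genotype label. It was placed in N2 from its title and strain, and its xpf-1 level is given in the results. The labels speak of biological triplicates while 6 libraries per group were analysed, so p-values measure the spread between these libraries, part of which may be technical.

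Per the submitters' processing notes, CASAVA, HISAT2 2.1.0 and featureCounts 1.5.0-p3 were used with genome build WBcel235. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads of near-identical paralogs, overlapping genes and antisense partners therefore cannot be told apart with certainty. The deposited table holds raw read counts for 46726 genes, of which 20292 had 0 counts in every library. It also holds FPKM values computed by the authors, in which the gene count is divided by a gene length and by the library's total count. With the deposited gene length this formula gave the deposited FPKM, within 1e-06 of its value, for 73.55% to 76.21% of the genes with a count in a library. FPKM values were not used in any test. The authors also deposited counts divided by 1 size factor per library, a signal on a normalised count scale. Per the file headers, the authors computed a log2 fold change of xpf-1 over N2 for each gene. Per the file headers, the authors also computed a p-value and an adjusted p-value for each gene, with a testing tool that is not given in the sources used here. The count columns were used for every test, and the authors' comparison columns only for an overlap of calls. Per the file headers, gene lengths and coordinates come with the deposited table, and those coordinates are the ones printed. Gene IDs were matched to current symbols through a reference name table, which held 43623 of the 46726 IDs.

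Total counts ran from 18407182 to 22817135 per library. With 6 libraries per group and a biological coefficient of variation of 9.62%, small fold changes of well-covered genes pass the test. In data simulated from these libraries over 14105 genes, 40% of genes changed 1.25-fold were recovered, 72% of those changed 1.5-fold, 88% of those changed 2-fold and 92% of those changed 4-fold. Among simulated genes with at least 50 counts, a limit chosen after these shares were seen, they were 51.4%, 94.6%, 100% and 100%. Of 154 simulated calls, 8 were unchanged genes. The simulation changed 50 genes at each fold, a much smaller share than the 59.7% of tested genes called in the real comparison. Recovery and false calls depend on that share, so these values need not hold for the real comparison.

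Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr, TMM factors were computed, and the quasi-likelihood test with robust dispersion was run on xpf-1 against N2 without covariates. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. CPM values are counts scaled by the TMM-adjusted library sizes. Values are mean ± SD over the 6 libraries of a group. Log2 fold changes are xpf-1 over N2 with their standard error. Where a group had 0 reads over its 6 libraries, the fold was bounded with 3 reads over the group. Such bounds and counting intervals (exact Clopper-Pearson, 95%) cover counting error only.

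A total of 48 gene lists was fixed before the data were examined. They cover DNA repair, lipid and energy metabolism, histones and acetylation, protein homeostasis, stress and immune responses, and markers of tissues and stages. The mitochondrially encoded list was matched by chromosome and biotype because the deposited table names those genes by another scheme. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 48 lists, and again with a correlation estimated per list. Genes named in the text follow a rule fixed at the same time. The rule takes xpf-1, mys-1, nhr-49, sbp-1 and fat-1 to fat-7. It adds the 15 largest changes each way among protein-coding genes whose groups did not overlap and whose higher mean was at least 5 CPM. It also adds the 10 smallest adjusted p each way, and up to 4 members per list with the smallest adjusted p, or the 2 of highest mean CPM where none passed. The text names a subset of these genes. Genes named outside the rule are said to be so.

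Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, a stricter threshold, a test against a 1.5-fold change, the replicate number as a block, a split into replicates 1 to 3 and 4 to 6, each library left out, the other reading of the N2 replicate 6 label, other gene classes in the totals and surrogate variables from sva 3.50.0. Alternatives for tables of normalised values alone did not apply. Further alternatives chosen after seeing the data are named as such in the closing section. For the splits of the samples, 100 of the 462 ways to part the 12 libraries into 6 and 6 were fitted, the real one included.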

Results

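The series compared mRNA of day-7 adult N2 worms with that of xpf-1 mutants, in whole animals grown on a bacterial lawn. XPF-1 is the catalytic subunit of the structure-specific nuclease that cuts damaged DNA in nucleotide excision repair and also acts in crosslink repair. The title of the series names persistent DNA damage, lipid metabolism and histone acetylation by the acetyltransferase MYS-1, the worm Tip60. There were 6 libraries per group. Total counts were 20463645 ± 1511000 in N2 and 20584441 ± 1488000 in xpf-1 (SD, n = 6 each), with a range over libraries of 18407182 to 22817135. N2 libraries had 18780 ± 319 genes with a count and xpf-1 libraries 20226 ± 403, and the ranges did not overlap.

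The targeted gene separated the groups. The xpf-1 transcript (WBGene00008140, chromosome II, 11696171 to 11705359, plus strand, WBcel235) stood at 73.01 ± 7.19 CPM in N2 and 11.7 ± 1.57 CPM in the mutant, which is 16% of the N2 level (SD, n = 6 each). The span of another gene overlaps that of xpf-1, so some reads can be shared. The tm2842 allele is a partial deletion, so reads can remain. Counts over the whole gene cannot separate fewer transcripts from reads missing over the deleted part. The log2 fold change was -2.64 ± 0.08 (SE), with a 95% interval of -2.82 to -2.46. All 6 mutant libraries lay below all 6 N2 libraries, and the two-sided exact permutation p was 0.0022, the smallest that 924 splits allow. The library titled N2 replicate 6, whose genotype label names the mutant, had 1468 xpf-1 reads, within the N2 range of 1192 to 1758 and above the 213 to 304 reads of the mutant libraries.

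**Figure D1:**
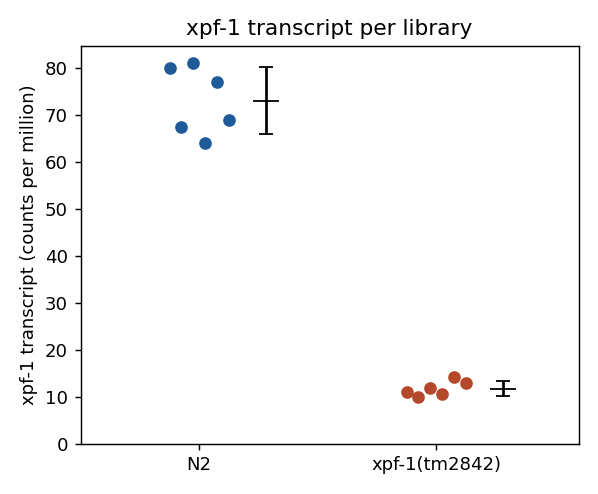
xpf-1 transcript in CPM (library-scaled counts) for each library (points), with the group mean and SD beside them (n = 6 per group). The N2 mean is 73.01 and the mutant mean 11.7, with no overlap between groups.

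Which transcripts differed between the mutant and the wild type was asked over all genes. Of 14248 genes tested, 8509 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4291 higher and 4218 lower in xpf-1. The changes were mostly small: the median absolute log2 fold of the called genes was 0.49, and 887 genes rose and 357 fell by at least 2-fold. All 6 libraries of one group lay beyond all 6 of the other for 2543 of the higher and 2886 of the lower genes, where chance gives 0.22% of genes. Protein-coding genes made up 4147 of the higher and 4151 of the lower calls. A test against a 1.5-fold change left 1643 genes, 980 higher and 663 lower. The authors' deposited table called 8826 genes, of which 8122 were among the 8509, each with the same sign.

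The largest increases were in genes with almost no reads in N2. F56A4.3 rose from 0.0612 ± 0.0841 to 14.3 ± 2.85 CPM, and scl-24, a gene of a secreted cysteine-rich family, from 0.431 ± 0.470 to 23.8 ± 3.44 CPM (SD, n = 6). The neighbouring genes pud-3 and pud-4 rose by 5.15 ± 0.29 and 4.04 ± 0.15 log2 units (SE). The annotated spans of these 2 genes overlap, so their split of reads is uncertain. The scaffold gene ccm-2 rose from 4.95 ± 0.718 to 54.9 ± 6.91 CPM. The secreted protease gene hch-1, which acts in hatching, went from 3.68 ± 0.478 to 29.3 ± 3.35 CPM, and the lipocalin gene lpr-3 of the apical extracellular matrix from 3.41 ± 0.581 to 25.5 ± 2.29 CPM. Among abundant genes, Y69H2.3 rose from 415 ± 33.4 to 1862 ± 114 CPM. The innate immune adaptor tir-1 rose from 120 ± 7.83 to 321 ± 17.8 CPM.

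The largest decreases were in genes with almost no reads in the mutant. Y73B3A.1 had 10155 reads over the 6 N2 libraries and 2 over the 6 mutant libraries, a ratio of 5110 with a counting interval of 1410 to 42200. Y73B3A.4 and T08D2.6 had 0 reads in the mutant and were at least 818-fold and at least 326-fold lower. These 3 genes lie at the left end of chromosome X, in a run of 20 genes from 32451 to 252767 that each kept under 10% of the N2 mean. The C-type lectin clec-190 on chromosome IV fell from 57.02 ± 5.42 to 0.804 ± 0.310 CPM, and its neighbours M199.9 and col-135 fell by 7.42 ± 0.33 and by 3.97 ± 0.28 log2 units. F35F10.5 and exh-1 on chromosome V fell by 5.94 ± 0.20 and by 3.58 ± 0.11 log2 units. They lie in a stretch from exh-1, which starts at 3157095, to T20D4.10, which ends at 3401045. There C36C5.12, T28A11.19, T20D4.11 and T20D4.10 also kept under 10% of the N2 mean. So did T28A11.3, F35F10.7, C17B7.4, C17B7.10, C17B7.3 and T20D4.15, which are named outside the rule. The bounds of this stretch were set from these genes themselves. In the same stretch T28A11.2 fell from 141.6 ± 13.4 to 32.2 ± 2.54 CPM. Whether such losses follow from the loss of xpf-1 or from other differences between the strains was not tested. With N2 replicate 6 counted as a mutant, Y73B3A.1, Y73B3A.4, clec-190 and F35F10.5 did not pass (edgeR adjusted p 0.183, 0.109, 0.061 and 0.0754), with log2 folds of -2.57, -2.71, -2.87 and -2.51. That library had 2060, 455, 1086 and 272 reads of these genes, and each mutant library at most 25, so that reading of its label lowers these calls by construction. Among genes that stayed well covered, T24H10.4 fell from 122.1 ± 8.44 to 26.9 ± 1.85 CPM and exc-13 from 56.4 ± 2.81 to 8.07 ± 1.17 CPM.

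Of 48 gene lists, 10 passed camera at an adjusted p of 0.05 with the preset correlation, 4 higher and 6 lower. None of the 10 passed with an estimated correlation, where the smallest adjusted p was 0.33. When the 12 libraries were split in other ways, 16 of 100 splits, the real one included, called at least as many lists, so chance was not excluded for the number of called lists. Some of these splits held unequal shares of the groups and so kept part of the group difference. The one-way fry test, which compares a list with no other genes, passed 33 lists at an adjusted p of 0.05. Median, mean and camera direction differed in sign for 5 lists, none of which passed camera: mitochondrial beta-oxidation, lipid droplet and phospholipid synthesis, the MYS-1 complex, embryo markers and cuticle collagens. The counts of members that follow come from edgeR over all genes tested. Adjusted over the list alone, they were equal for 34 of the 48 lists, and the other lists' counts are given where they occur.

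Germline and oocyte transcripts were lower in the mutant. Of 52 markers, 46 fell and 2 rose, and adjusted over the list alone 47 fell and 2 rose. The median log2 fold was -0.75, with a camera adjusted p of 6.39e-15, against an adjusted p = 0.33 with an estimated correlation. The eggshell proteoglycan gene cpg-2 fell from 1148 ± 55.5 to 458 ± 40.7 CPM, the oocyte maturation factor oma-2 from 406 ± 27.3 to 167.7 ± 14.9 CPM, and the RNA-binding germline gene daz-1 from 97.4 ± 8.12 to 41.7 ± 4.28 CPM. Of the 57 sperm markers in the deposited table, only 20 had enough counts to be tested. Of these, 2 rose, 2 fell (1 and 1 adjusted over the list alone) and 16 did not pass. The median log2 fold of the 20 was 1.11, toward higher levels in the mutant, the largest of the 48 lists. This list did not pass camera with all libraries (adjusted p 0.156), but did as a rise without N2 replicate 4 (0.0158, median 1.83) and without N2 replicate 5 and xpf-1 replicates 1 and 5 (0.025, median 1.096). Among the tested markers spe-11, at 0.727 to 1.89 CPM in N2, rose by 1.29 ± 0.25 and spe-15 fell by 0.49 ± 0.09 log2 units.

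Cytosolic ribosomal protein genes were lower in the mutant, as were 46 of 52 germline and oocyte markers (median log2 fold -0.75). Of 81 ribosomal protein genes, 77 fell and 1 rose, with a median log2 fold of -0.58 and a camera adjusted p of 3.99e-19, against an adjusted p = 0.568 with an estimated correlation. The large-subunit gene rpl-28 fell from 795 ± 47.4 to 448 ± 18.9 CPM, rpl-11.1 from 1453 ± 118 to 703 ± 61.3 CPM and the small-subunit gene rps-15 from 2083 ± 143 to 1228 ± 53.7 CPM. The proteasome list was lower too, beside the same fall of germline markers, with 23 of 33 members lower and 1 higher (25 and 1 adjusted over the list alone), a camera adjusted p of 0.000555 and an adjusted p = 0.729 with an estimated correlation. The core subunit pas-7 fell from 304 ± 11.4 to 177 ± 8.53 CPM.

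Nuclear-encoded respiratory chain genes were mostly lower, in a comparison where 46 of 52 germline and oocyte markers fell. Of 42 such genes, 33 fell and 1 rose, with a median log2 fold of -0.25, a camera adjusted p of 7.55e-06 and an adjusted p = 0.33 with an estimated correlation. The ATP synthase subunit asg-1 fell from 297 ± 19.1 to 205.9 ± 10.03 CPM. Of 12 mitochondrially encoded genes, 4 fell and 0 rose, and this list passed camera without N2 replicate 5 (adjusted p 0.0181) and not with it (0.416). In that library mitochondrial genes took 0.884% of the counts, against 1.56% to 2.45% in the other libraries. Among the 28 genes of the TCA cycle, glyoxylate shunt and gluconeogenesis, 15 fell and 4 rose, with fbp-1 down from 120.7 ± 2.06 to 80.4 ± 3.55 CPM and the aconitase aco-1 up from 112 ± 8.53 to 167 ± 6.68 CPM. Of 18 glycolytic genes, 8 fell and 5 rose, and the hexokinase hxk-1 fell from 197 ± 12.9 to 98.2 ± 6.59 CPM. For trehalose and glycogen, 6 of 12 fell and 3 rose, among them the glycogen phosphorylase pygl-1, which fell by 0.64 ± 0.09 log2 units.

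Lipid genes moved in both directions, and none of the lipid lists other than the vitellogenins passed camera. The fatty acid synthase gene fasn-1 rose from 44.01 ± 5.14 to 141 ± 17.5 CPM (log2 fold 1.67 ± 0.08, edgeR adjusted p = 2.59e-12). In the 17-gene synthesis and elongation list, 6 rose and 5 fell, among the latter the ATP citrate lyase acly-2, which fell by 0.45 ± 0.05 log2 units. Of the 7 desaturases, fat-1, fat-2 and fat-4 rose by 0.19 ± 0.05, 0.18 ± 0.05 and 0.35 ± 0.05 log2 units. The others did not pass the test, with log2 folds of -0.02 ± 0.05 for fat-3, 0.08 ± 0.06 for fat-5, 0.08 ± 0.05 for fat-6 and 0.05 ± 0.08 for fat-7. With library totals only, fat-5 and fat-6 passed as well (edgeR adjusted p 0.0231 and 0.0143), as they did with upper quartile factors (0.0239 and 0.0141). fat-5 also passed without N2 replicate 2 (edgeR adjusted p 0.0195) and fat-6 among genes of at least 5 CPM in 6 libraries (0.0233). The call of fat-2 was lost without a low-count filter (0.0503) and that of fat-1 in replicates 1 to 3 alone (0.0792). Against a 1.5-fold change none of fat-1, fat-2, fat-4, nhr-49 and sbp-1 passed (edgeR adjusted p 1 each). Of 26 lipid regulators, 13 rose and 5 fell. The nuclear receptor nhr-49 rose from 112.9 ± 12.04 to 151 ± 6.79 CPM and nhr-25 from 3.04 ± 0.591 to 12.45 ± 1.13 CPM, while the SREBP homologue sbp-1 fell by 0.24 ± 0.08 log2 units (edgeR adjusted p = 0.0164). The sbp-1 call was lost without xpf-1 replicate 4 (edgeR adjusted p 0.0504), with library totals only (0.0896), with upper quartile factors (0.0984), with N2 replicate 6 counted as a mutant (0.101) and in replicates 1 to 3 alone (0.448), within a range of 1.58e-05 to 0.448 over the alternatives other than the test against a 1.5-fold change.

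For lipid breakdown, 10 of 31 mitochondrial beta-oxidation genes rose and 7 fell, and 7 of 21 peroxisomal ones rose and 3 fell (4 and 3 adjusted over the list alone). Of 12 lipases, 6 rose and 4 fell, with fil-1 up from 2.93 ± 0.758 to 18.6 ± 1.598 CPM. Lipid droplet, triglyceride and phospholipid genes split into 13 that rose and 12 that fell of 30. The phosphocholine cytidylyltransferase pcyt-1 rose from 123 ± 6.02 to 182 ± 8.19 CPM. The listed gene mdt-28 (sequence name F28F8.5) fell from 113 ± 5.92 to 68.7 ± 2.46 CPM. Whether this entry encodes a lipid droplet protein was not checked. Of 21 lipid-binding and transport genes, 10 rose and 3 fell (11 and 4 adjusted over the list alone), and lbp-9 fell from 466 ± 33.2 to 258 ± 21.6 CPM. Of the 6 vitellogenins, which encode yolk proteins, 5 rose and 0 fell, while 46 of 52 germline markers fell. Their median log2 fold was 0.79, with a camera adjusted p of 0.0256 and an adjusted p = 0.741 with an estimated correlation. The abundant vit-2 went from 2064 ± 260 to 3681 ± 1049 CPM, with mutant replicate 1 at 5730 CPM and the others between 2750 and 3650.

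The acetyltransferase gene named in the series title did not pass the test. mys-1 stood at 120 ± 6.92 CPM in N2 and 116 ± 5.31 CPM in xpf-1, a log2 fold of -0.06 ± 0.05 with an edgeR adjusted p of 0.344. Of the 12 genes of its complex, 4 rose and 5 fell. The largest rise was in trr-1, at 0.65 ± 0.09 log2 units, but that call and the one of epc-1 were lost once the trend of counts with gene length was removed, where their log2 folds were 0.07 and 0.09 (edgeR adjusted p 0.223 and 0.0951). Of 30 acetyltransferase, deacetylase and acetyl-CoA supply genes, 6 rose and 12 fell, and the acetyl-CoA synthetase acs-19 fell from 177 ± 13.95 to 114 ± 8.21 CPM. Among 43 histone genes, 11 rose and 8 fell. The linker histone hil-3 rose from 42.3 ± 3.33 to 94.1 ± 8.86 CPM and his-68 fell from 18.2 ± 1.59 to 7.40 ± 0.795 CPM. Histone gene copies share sequence, so their single values are uncertain.

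More DNA repair transcripts fell than rose, in a comparison where 46 of 52 germline and oocyte markers also fell (median log2 fold -0.75). Of 13 nucleotide excision repair genes, 9 fell, xpf-1 among them, and 1 rose (9 and 2 adjusted over the list alone), with a camera adjusted p of 0.0375 and an adjusted p = 0.335 with an estimated correlation. The fall of xpf-1 itself is fixed by the genotype. Without it, 8 of 12 fell and 1 rose, with a median log2 fold of -0.21, and the list did not pass camera (adjusted p 0.128), an alternative chosen after seeing the data. The call was also lost with library totals only (0.0557), in a range of 0.00847 to 0.128 over the alternatives with the preset correlation. The partner of XPF-1 in the nuclease, ercc-1, fell from 112 ± 4.06 to 71.9 ± 4.76 CPM and the damage recognition gene xpa-1 from 118.9 ± 7.56 to 85.7 ± 3.09 CPM. Of 36 double-strand break and crosslink repair genes, 22 fell and 6 rose, with a camera adjusted p of 0.0232 and an adjusted p = 0.754 with an estimated correlation. The translesion polymerase polh-1 fell from 60.7 ± 1.81 to 37.3 ± 2.12 CPM and the meiotic nuclease spo-11 from 86.7 ± 4.54 to 55.6 ± 3.38 CPM. In the 21-gene damage response list, 11 fell and 5 rose. The pro-apoptotic egl-1 rose from 4.97 ± 1.18 to 11.8 ± 1.82 CPM and the caspase ced-3 fell from 68.8 ± 5.85 to 46.5 ± 3.68 CPM.

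Markers of molting and of the hypodermis were higher on balance, in a comparison where 46 of 52 germline and oocyte markers fell (median log2 fold -0.75). Of 19 molting larva markers, 12 rose and 4 fell, with a median log2 fold of 0.65, a camera adjusted p of 0.0221 and an adjusted p = 0.335 with an estimated correlation. The apical matrix genes fbn-1 and noah-2 rose from 6.89 ± 0.646 to 34.1 ± 3.82 CPM and from 3.90 ± 0.767 to 20.2 ± 2.83 CPM. Of 14 hypodermis and seam markers, 9 rose and 2 fell, with a camera adjusted p of 0.0433 and an adjusted p = 0.33 with an estimated correlation. That call was lost with the length trend removed (0.188), with a replicate block (0.0556), without N2 replicate 2 (0.0656) and without xpf-1 replicate 4 (0.0502), in a range of 0.025 to 0.188 over the alternatives with the preset correlation. With the length trend removed the median log2 fold was 0.08, against 0.33. Of 76 cuticle collagens, 27 rose and 31 fell, with dpy-17 up from 9.90 ± 1.47 to 30.7 ± 2.95 CPM and col-80 down from 30.2 ± 2.395 to 8.15 ± 1.503 CPM.

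Of the stress response lists, only that of the endoplasmic reticulum passed camera, beside the fall of 46 of 52 germline markers. Of 19 endoplasmic reticulum unfolded protein response genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone), with a camera adjusted p of 0.0221 and an adjusted p = 0.604 with an estimated correlation. The BiP chaperone hsp-4 rose from 231 ± 10.1 to 298 ± 16.06 CPM. The camera calls of this list and of the vitellogenins were lost with the length trend removed (0.0578 for both), where their median log2 folds were 0.20 and 0.48, against 0.25 and 0.79. In the mitochondrial unfolded protein response list, 4 of 11 fell and 0 rose, with hsp-60 down from 37.1 ± 4.94 to 21.2 ± 3.19 CPM. Of 18 heat shock genes, 6 rose and 2 fell (5 and 2 adjusted over the list alone), and of 31 oxidative stress genes, 6 rose and 14 fell, with the manganese superoxide dismutase sod-2 down from 218 ± 12.7 to 144 ± 5.84 CPM. Of 27 DAF-16 targets, 4 rose and 9 fell. Of 34 autophagy and lysosome genes, 20 rose and 8 fell, with the cargo receptor sqst-1 up from 144 ± 6.60 to 232 ± 14.2 CPM.

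**Figure D2:**
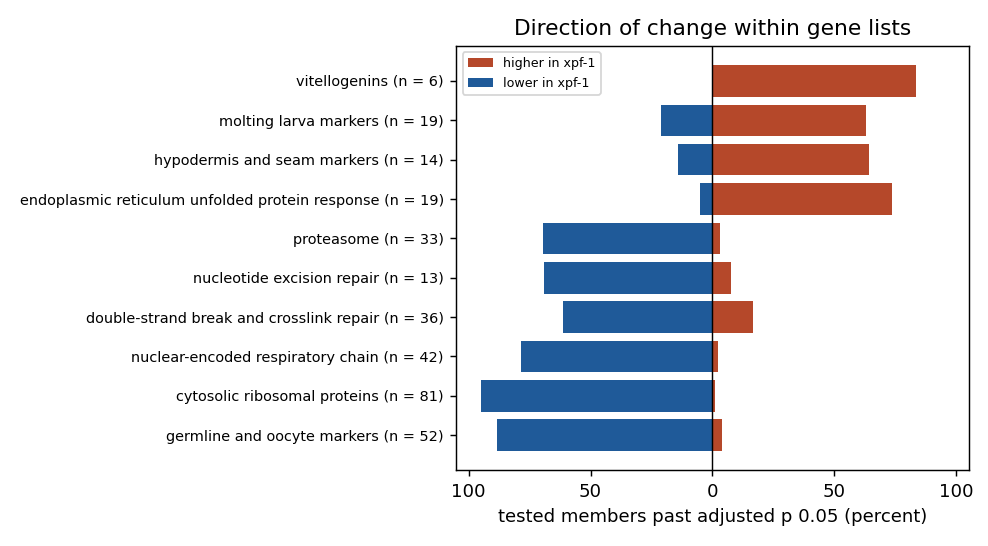
Share of tested members (percent, horizontal axis) that passed an edgeR adjusted p of 0.05 in each of the 10 gene lists called by camera with the preset correlation, higher in xpf-1 to the right and lower to the left, with the number tested beside each name. The ribosomal protein list shows 77 of 81 members lower.

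Detoxification and immune lists had members that moved both ways, and none passed camera. Of 38 glutathione S-transferases, 6 rose and 13 fell, of 58 cytochrome P450s 20 rose and 12 fell, and of 58 UDP-glucuronosyltransferases 16 rose and 8 fell. The glutathione S-transferase gst-43 fell from 25.5 ± 2.32 to 8.39 ± 0.949 CPM, cyp-13A5 rose from 21.2 ± 1.07 to 51.5 ± 4.27 CPM and ugt-48 from 20.9 ± 0.635 to 53.2 ± 3.73 CPM. Of 58 innate immune effectors, 19 rose and 20 fell (20 and 22 adjusted over the list alone), and the lysozyme lys-4 fell from 263 ± 26.8 to 92.6 ± 2.92 CPM. Of 103 C-type lectins, 35 rose and 26 fell, with clec-266 up from 579 ± 45.3 to 1289 ± 83.03 CPM. Of 21 epidermal antimicrobial peptides, 9 rose and 4 fell (9 and 5 adjusted over the list alone). The intracellular pathogen response list had 9 of 43 higher and 23 lower, with pals-14 down from 15.6 ± 2.51 to 5.51 ± 0.855 CPM and irg-1 up from 4.75 ± 1.01 to 12.03 ± 0.815 CPM.

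Markers of other tissues and stages gave no called list. Of 34 neuron markers, 13 rose and 2 fell (12 and 2 adjusted over the list alone), of 26 insulin-like peptides 12 rose and 5 fell, and ins-19 rose from 52.2 ± 6.65 to 117 ± 8.11 CPM. Of 28 embryo markers, 9 rose and 10 fell (9 and 11 adjusted over the list alone), with pal-1 down from 243 ± 9.85 to 129 ± 3.98 CPM and elt-1 up from 23.1 ± 2.47 to 51.04 ± 3.78 CPM. Of 24 intestine markers, 8 rose and 7 fell (9 and 7 adjusted over the list alone). Of 23 body wall muscle markers, 7 rose and 10 fell (7 and 11 adjusted over the list alone), and of 8 pharynx markers 3 rose and 2 fell. The list of coelomocyte, gonadal sheath, spermatheca and uterus markers had 5 of 17 higher and 4 lower. None of the 5 ribosomal RNA genes tested passed edgeR's test, and rrn-3.1 stood at 15520 ± 8231 CPM in N2 and 25670 ± 15590 CPM in xpf-1. Ribosomal RNA took 0.0332% of the counts of N2 replicate 5 and between 1.72% and 5.46% in the other libraries.

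**Figure D3:**
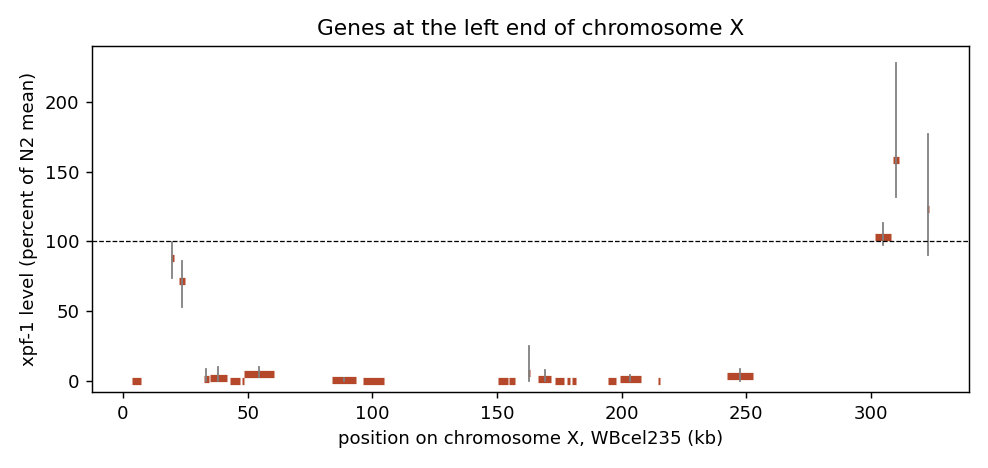
Level in xpf-1 as a percent of the N2 mean (vertical axis) for genes with at least 60 N2 reads at the left end of chromosome X (horizontal axis, position in kb). Red bars span each gene at its mean and grey lines run from the lowest to the highest of the 6 mutant libraries. The 20 genes from 32451 to 252767 keep under 10% on average, and gcp-2.1, the next gene to the right, keeps 103%. That gene was chosen after its values were seen.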

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

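The tests of chance clustering, of a missing stretch of X and of read depth were chosen only after the result was seen. In 322 sets of 6 values, for named genes and library measures in each group, 36 had 1 library far from the other 5. About 16 would be expected by chance if the sets were independent. They come from the same libraries and from genes that move together, so the excess is no measure against chance.

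Mutant replicate 1 accounted for many of the 36 sets. It had the highest CPM of its group for vit-2 (5730), vit-6 (6050), vit-4 (178), fasn-1 (175), acs-1 (62), trr-1 (127), epc-1 (188), fbn-1 (41.4), pgp-1 (16.6), ajm-1 (70.7), gst-43 (10.3) and F35F10.5 (0.376), and its vitellogenin share of counts was 1.92%, against 0.939% to 1.24% in the other mutant libraries. N2 replicate 2 stood apart in others. It was highest among N2 for fil-1 (4.41), lipl-7 (53.5), mdt-28 (125), rpl-28 (890), rps-15 (2370), nlp-27 (80.5), pals-14 (20.4), ins-19 (64.6) and F56A4.3 (0.226). It was lowest for T24H10.4 (106), hda-6 (68.4), ptr-23 (15.5) and ajm-1 (29.1 CPM). The rest were spread over other libraries. N2 replicate 1 was lowest for pygl-1 (141) and pas-7 (282), N2 replicate 4 highest for scl-24 (1.36) and spe-11 (1.89), and mutant replicate 4 highest for ctb-1 (1590) and rpn-12 (160). Mutant replicate 5 was lowest for ugt-48 (45.9) and phat-3 (2.56) and the only mutant library with reads of Y73B3A.1 (0.109). Mutant replicate 6 was highest for M199.9 (0.170 CPM).

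Genes with almost no reads in the mutant lay beside each other. Of 13919 genes with at least 60 N2 reads, 44 kept under 10% of their N2 level, and 22 of these were on X. Others lay in the stretch of chromosome V from exh-1 to T20D4.10 given in the results. The 44 genes formed 27 adjacent pairs, more than the at most 4 in 10000 shuffles of their positions (permutation p 1e-04, the smallest these can give). Most of these pairs lie in the run on X, which was seen before this test was chosen. Some neighbours also overlap, so the p-value is no measure against chance. Lower depth is argued against, since mean totals of the mutant libraries were 0.121 M counts above those of N2, within the SD of 1.5 M (exact permutation p 0.887). The run of 20 genes at the left end of X, whose bounds were set from the lost genes themselves, may be missing from the mutant strain. In single mutant libraries, however, tmed-12 reached 24.9% of its N2 level, with 4 reads over the group, and Y73B3A.21 and Y73B3A.18 reached 10.2%, the latter with 30 reads over the group. A deletion and a silenced stretch cannot be told apart from transcript counts, because both would leave few reads. The reads that remain do not exclude a deletion, since a few can also come from similar sequence elsewhere. VY35H6BL.2 and VY35H6BL.1 to the left of the run kept 88.0% and 71.6%, and CE7X_3.1, further left, had 84 reads in N2 and 0 in the mutant. These 6 genes were chosen after their values were seen.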

How the results depend on the processing

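The alternatives that removed the gene-length trend, left out N2 replicate 5 with mutant replicates 1 and 5, or took xpf-1 out of its list were chosen after seeing the data. No named gene or list reversed under any setting run where it was called in the main fit or in that setting. Sign changes of values called in neither were not counted as reversals. The count of 8509 genes moved by over 1.5 times only in the test against a 1.5-fold change (1643 genes, 980 higher and 663 lower). Other settings gave 6593 (replicates 1 to 3 alone) to 9249 (no low-count filter), and leaving out each library gave 8195 to 8594 genes and 9 to 11 lists. Over the other alternatives run for lists with the preset correlation, 7 to 12 lists passed. Without N2 replicate 5 and mutant replicates 1 and 5 there were 7647 genes. Counting N2 replicate 6 as a mutant gave 6652. Library totals only and upper quartile factors put 58.8% and 59.4% of calls on the higher side, against 50.4%. With the gene-length trend removed it was 44.5%, and 24 of the genes called with and without it had opposite signs. Replicate numbers did not pair the samples: 1 of 6 numbers correlated above 0.1, and 1 of 6 N2 libraries correlated best with its own number. The replicate block gave 8536 genes, and hypodermis and seam markers then had an adjusted p of 0.0556.

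No list passed with an estimated correlation (0 lists, against 10). The adjusted p values were then 0.335 for nucleotide excision repair and for molting larva markers, 0.754 for double-strand break repair, 0.741 for vitellogenins, 0.568 for ribosomal proteins, 0.729 for the proteasome, 0.604 for the endoplasmic reticulum response, and 0.33 for respiratory chain, germline and hypodermis lists. For nucleotide excision repair, library totals only gave 0.0557, and taking the mutated gene out of the list gave 0.128. With the length trend removed, vitellogenins and the endoplasmic reticulum response had 0.0578 and hypodermis 0.188. Without each library, hypodermis ran from 0.0336 to 0.0656. The cause of these losses was not tested. The log2 fold of gene xpf-1 ran from -2.69 to -2.60 without each library and from -2.80 to -1.90 over the other alternatives, the weakest with N2 replicate 6 counted as a mutant. Over the settings run, 81 of the named genes' values lost the call and 6 gained one (60 of the losses came from the test against a 1.5-fold change, and these include nhr-49, sbp-1, fat-1, fat-2, fat-4, ercc-1, xpa-1, ced-3, spo-11, acly-2, pcyt-1, vit-2, trr-1, epc-1, acs-19, fbp-1, aco-1, pygl-1, asg-1, hsp-4, sod-2 and spe-15), while 18 list values lost it and 4 gained one. Depth limits what can be seen of small changes in genes with few counts.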

Other observations

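The counts of splits for each list, 200 of the simulated unchanged lists and the test of the spread of germline markers were chosen only after the result was seen.

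Only 1 of 100 splits of the 12 libraries, the real one, gave as many as 8509 genes, and the highest other split gave 28. The count thus went with the N2 and mutant labels. Every other split drawn mixes N2 and mutant libraries, so the group difference adds to the spread within each side and lowers the count. These splits therefore cannot tell how many genes chance alone would call, and no conclusion on chance was drawn from them for the number of genes. Chance cannot be excluded for the number of lists, since 16 of 100 splits, the real one included, gave at least 10 and the highest other gave 13. In simulated data with independent genes 1.99% of 201 unchanged lists had a camera p below 0.05. Of these lists 200 were added after the first had a p of 0.0396, and why the other splits called lists was not tested. List by list, no other split drawn gave as small a camera p for ribosomal proteins, germline markers or molting larva markers. As small a p came from 4 splits for the respiratory chain, 5 for hypodermis, 8 for nucleotide excision repair, 9 for the endoplasmic reticulum response, 11 for the proteasome, 17 for vitellogenins and 20 for double-strand break repair, the real one included. No other split drawn gave as large a median log2 fold for any of the 10 called lists. The margin was smallest for nucleotide excision repair (under 0.01), molting larva markers (0.63 against 0.65) and vitellogenins (0.76 against 0.79). For some uncalled lists, glycolysis among them, no other split gave as large a median either. Splits that mix the groups hold less of the group difference, so these medians give the called lists no added weight.

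Molting larva markers had a median log2 fold of 0.65. Late embryos or larvae among the mutant worms would bring pharyngeal cuticle genes with them, but the median log2 fold of the 7 of 19 such genes that could be tested was 0.02, and none rose or fell. These 7 genes stood between 0.536 and 2.82 CPM in N2 and the untested ones had 86 reads in N2 and 75 in the mutant, so the test rests on low counts. Genes of greater length were counted more in the mutant. Random lists matched on length and expression had a middle value of 0.236 for their medians, so part of the 0.65 may go with these traits. The upper bound of their 95% range was 0.50, with draws that took genes as independent. What raised these genes was left open.

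Ribosomal protein genes had a median log2 fold of -0.58. Lists matched on length and expression reached -0.135 at the lower bound of their 95% range, which argues against gene length as the whole cause. Median gene lengths were 631 in the list and 663 in the draws, but the closeness of the match in expression was not checked. The draws took genes as independent, while this list had an estimated correlation of 0.473, so their range may be too narrow. A smaller germline share of the animal may lower these genes too: 46 of 52 germline markers fell, with a median log2 fold of -0.75. Their log2 folds had an SD of 0.407 against a median standard error of 0.062, but 44 of the 47 other lists also had an SD over 2 times their median standard error, so this spread cannot tell a loss of germline from a change within it.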
